A study of Mus musculus with 4 samples.

How the data were processed

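Gene expression was measured in cells labelled as peritoneal macrophages (PEC in the sample titles) from wild-type and LysM-St18flox mice, unstimulated (0 h) or after 3 h with lipopolysaccharide (LPS), the outer membrane component of Gram-negative bacteria that activates Toll-like receptor 4. Per the labels' protocols, mice received 4% thioglycollate, an irritant that draws leukocytes into the peritoneal cavity, and the lavage was collected after 3 days. Cells were kept in medium with 10% serum, RNA was extracted with a phenol reagent, and 100 ng of total RNA was labelled with Cy3. The dose of LPS is not given in the sources used here. Each of the 4 groups (2 genotypes, each at 0 h and 3 h) had 1 array, and all 4 arrays lay on 1 slide and were scanned in 1 session, so neither could act as a batch.

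The deposited spot intensity values are scanner output of Agilent 1-colour arrays. Per the file headers and the submitters' processing notes, they were made with Agilent Feature Extraction 11.0.1.1. Per the file headers, the processed intensity of a spot is its signal after background subtraction and spatial detrending, with no normalization between arrays, and each spot carries flags for signal well above background, saturation and outlying pixels. The deposited value table holds log2 values. No source used here states its normalization or its filter. All 4 of its columns had a median of 9.58. Each column correlated with the log2 signal of its own array at 0.99994 or more and with that of another array at 0.991 or less. It lists 25482 probes, of which 99.98% were well above background on all 4 arrays. Its scale and direction were taken from these comparisons, and the centring step behind it stays unknown.

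Each array held 59305 non-control spots of 56605 probes. The scanner files give an accession for each probe and no gene symbol, so names were taken by matching accessions without version numbers to the RefSeq gene table of assembly GRCm38.p6. Of 35886 RefSeq probes, 32994 matched 1 gene symbol each, giving 22911 genes, none matched several, and 23611 of all probes had no symbol here. The file headers name another genome build, so that table was used for names and for the order of genes only, and no coordinates are given. As the headers' columns hold median and not mean spot signals, the normexp alternative used median signals.

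From the deposited intensities, spots of one probe were averaged on the log2 scale, and each array's 75th percentile was subtracted. Control spots and spots with an outlier flag were left out. A gene was represented by its brightest probe over the 4 arrays. It counted as measured in a comparison when that probe was well above background, not saturated and free of outlier flags on every array of the comparison. With 1 array per group no p-value was computed. An additive model of genotype and time would leave 1 degree of freedom and take the interaction as error, and it was not run. Counts are of genes at least 2-fold apart (a log2 difference of 1 or more). A gene above background on 1 side only was given as a bound, "at least N-fold". The bound is the bright side's normalized value against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array.

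A set of 32 gene lists was written beforehand: 20 pathways, 10 sets of cell type markers (macrophage, large peritoneal macrophage, neutrophil, B cell, T and NK cell, mast cell, eosinophil, dendritic cell, mesothelial and fibroblast, erythroid) and 2 checks. Of their names, 10 had no probe with that symbol. A list's median log2 difference over its measured members was set among the medians of 10000 random lists of the same size, drawn from genes of similar signal (20 signal bins). This percentile describes these arrays and is not a test of the conditions.

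The genes named were fixed by a rule. The rule took the 12 largest higher and 12 largest lower differences of each LPS response and of each genotype difference, the 10 largest genotype differences of one direction at both times, and the 8 largest in each direction of the difference of the LPS responses. Clone names, predicted genes and accessions were excluded. St18, Vegfa, Lyz2, Tnf, Il6, Il1b, Il10, Il12b, Ifnb1, Nos2 and Ptgs2 were always included, with up to 4 members of a list and up to 3 bounds per comparison and direction. Some list members that the rule names are not reported here. Groups, comparisons, lists, the rule for named genes and the alternatives to be tried were set before the data were examined.

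Between 52.2% and 55.6% of the spots were well above background on an array, and no spot was saturated. Probes printed 10 times on an array had a median standard deviation of 0.04 (log2) at wild-type 0 h, 0.04 at wild-type 3 h, 0.03 at LysM-St18flox 0 h and 0.04 at LysM-St18flox 3 h. The corresponding standard deviation of a difference between single spots of 2 arrays was 0.05. This covers spot error only, not mice, cultures or labelling, and the number of arrays limits the precision of every difference. The computation was run on simulated data with spot error only, for the 12589 genes of the wild-type LPS comparison. Of 50 genes changed 2.5-fold, 100% were called, of 50 changed 1.5-fold 0% were, and no unchanged gene was. With so small an error and a 2-fold threshold, this outcome was set in advance. It checks the code and gives no rate of true or false calls between arrays.

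Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median of detected probes, the deposited value table, the mean of all probes of a gene, no background filter, a stricter filter on dim probes, and thresholds of 1.5-fold and 3-fold. A count requiring 2 probes of a gene to differ was added after the data had been seen. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.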

Results

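The arrays compared cells of 2 genotypes, each at 0 h and after 3 h of LPS, with 1 array in each of the 4 groups. The labels give the cell type as peritoneal macrophage, while the sample titles read PEC, a usual short form of peritoneal exudate cells, which hold other cell types too. LysM, the lysozyme promoter in the genotype's name, is commonly used to drive recombination in macrophages and neutrophils, and St18 encodes a zinc finger transcription factor of the MYT family. The 75th percentile of the processed signal was 672 at wild-type 0 h, 755 at wild-type 3 h, 1067 at LysM-St18flox 0 h and 882 at LysM-St18flox 3 h. No difference reported here has a replicate check, and all values are differences between single arrays.

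The first question was whether St18 signal followed the genotype labels. One of 2 St18 probes was well above background in both wild-type arrays, with a normalized log2 signal of -1.31 at 0 h and -1.66 at 3 h. The same probe was not well above background in either LysM-St18flox array. St18 was therefore at least 7.07-fold lower in LysM-St18flox cells at 0 h and at least 8.48-fold lower at 3 h. With normexp correction the bounds were log2 -2.05 and -1.74, against -2.82 and -3.08 here. The second St18 probe was not well above background on any array, and whether either probe lies in the altered part of the gene is not given in the sources used here, so a probe outside it would check nothing.

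Vegfa encodes the angiogenic growth factor VEGF-A. The brightest of its 4 probes was 9.49-fold lower after LPS in wild-type cells (log2 difference -3.25) and 11.7-fold lower in LysM-St18flox cells (-3.55). The other probes gave -2.30, -1.13 and 0.51 in wild-type cells and -2.48, -1.59 and -0.64 in LysM-St18flox cells. Between genotypes the brightest probe differed by 0.29 at 0 h (higher in LysM-St18flox) and by -0.01 at 3 h. Those other probes ranged from 0.12 to 2.07 at 0 h, the highest from the dimmest of the 4 probes, and from -0.07 to 0.93 at 3 h. With the mean of all probes the genotype difference was 0.77 at 0 h and 0.24 at 3 h.

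**Figure D1:**
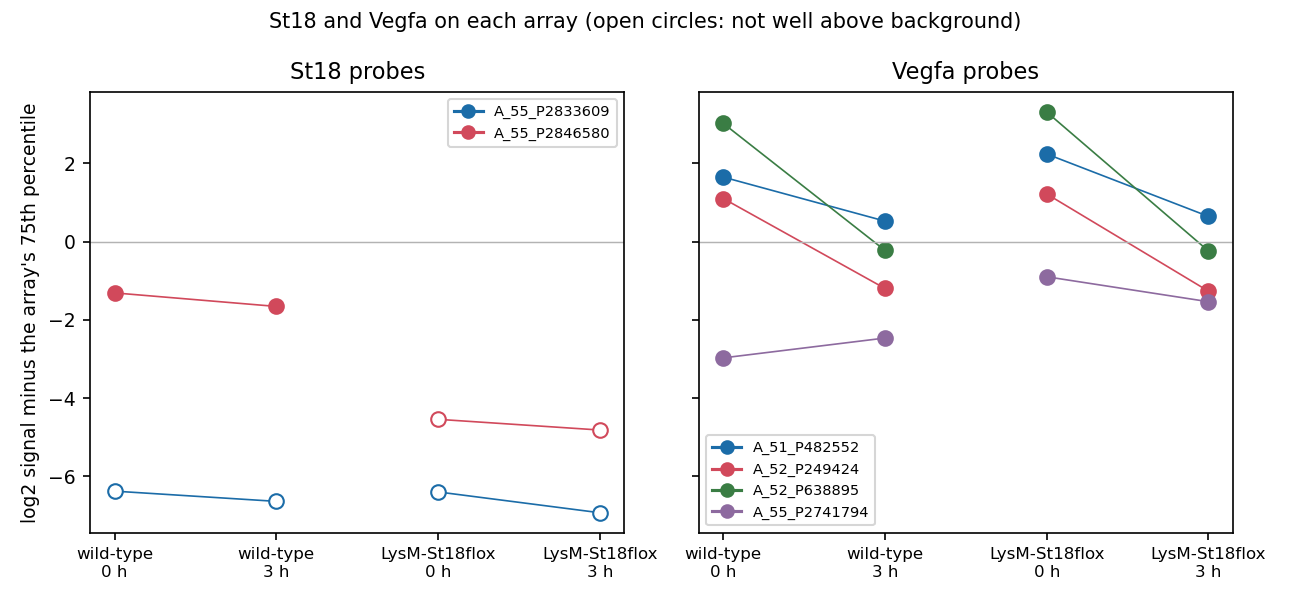
Normalized log2 signal (log2 signal minus the array's 75th percentile, y axis) of each St18 probe (left) and Vegfa probe (right) on the 4 arrays (x axis), 1 array per group, with lines joining 0 h and 3 h of one genotype. Filled circles are well above background and open circles are not. The brighter St18 probe lies at -1.31 and -1.66 in wild-type cells and is open in both LysM-St18flox arrays, and the brightest Vegfa probe lies lower at 3 h in both genotypes.

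The LPS response in wild-type cells asked which genes differed after 3 h of stimulation. Cxcl10, a chemokine for activated T cells, was 3326-fold higher (log2 difference 11.70), Ifit1, an interferon-induced antiviral gene, 850-fold, and the guanylate-binding protein gene Gbp5 576-fold. Next were the neutrophil chemokine gene Cxcl3 (491-fold), the cytokine signalling inhibitor Cish (268-fold), Cxcl1 (262-fold), Rnd1 (238-fold) and Ccl5 (193-fold). They were followed by Il1b (180-fold), the cholesterol 25-hydroxylase gene Ch25h (169-fold), Il1a (163-fold) and Tnfsf15 (162-fold). The lower values included those of Cebpa, a myeloid transcription factor gene, at 14.4-fold lower and Lpin1, a phosphatidate phosphatase gene, at 22.8-fold lower.

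Il6 was not well above background in unstimulated wild-type cells and was at least 570-fold higher at 3 h. The corresponding bounds were at least 215-fold for Edn1, which encodes endothelin-1, 187-fold for Ifit2, 128-fold for Il10, 61.8-fold for Ifnb1 and 46.0-fold for Il12b. Ptgs2, which encodes the inducible cyclooxygenase, was 136-fold higher, Tnf 46.6-fold and Nos2, which encodes inducible nitric oxide synthase, 45.3-fold. Other lower genes in wild-type cells were Galnt9 (25.5-fold), Lpar6 (20.7-fold), Ankrd37 (log2 -4.32), Vamp1 (18.2-fold), Fam78a (17.8-fold), Fbxo31 (16.4-fold), Smad6 (15.7-fold), Nfic (14.7-fold), Lyl1 (14.4-fold) and Gpr146 (13.6-fold). Fbxo32 (at least 41.6-fold), Zfp395 (36.7-fold) and Usp2 (36.2-fold) were lower and not well above background at 3 h.

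All 17 measured members of the LPS-induced cytokine and chemokine list were at least 2-fold higher in wild-type cells, with a median log2 difference of 5.54, and 11 further members had bounds above 0. The interferon-stimulated list had 31 of 31 measured members at least 2-fold higher (median 4.07), including Rsad2 (7.21), Ifit3 (6.99) and Cmpk2 (6.99). Feedback inhibitors of Toll-like receptor signalling had 18 of 21 members higher (median 3.11), with Socs3 at 6.29, Nfkbiz at 5.87 and Socs1 at 5.79. All 3 medians lay at percentile 100 among matched random lists. In the hypoxia and glycolysis list, 2 of 30 members were higher and 4 lower (median -0.39, percentile 0.02), among them Egln3 at -2.95, which encodes an oxygen-sensing hydroxylase, and Hif1a at 1.80. With the mean of all probes of a gene that median was -0.10. LPS-induced enzymes and surface molecules had 16 of 20 members higher and 1 lower (median 3.24). NF-kB and AP-1 factors had 10 of 20 higher and 3 lower (median 0.997), and p53 targets and apoptosis genes 7 of 18 higher and 2 lower (median 0.69). Macrophage markers had 4 members higher and 4 lower, with Cx3cr1 at -1.72.

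Of 12589 genes measured in wild-type cells, 1138 were at least 2-fold higher and 1464 at least 2-fold lower at 3 h, which together made 20.7%. The median difference over these genes was -0.11. A further 344 genes were higher and 397 lower by a bound of at least 2-fold. Among 705 genes past 2-fold with a second measured probe, that probe was also past 2-fold in the same direction for 55.2%. Lyz2, the lysozyme gene, was 2.78-fold higher (1.47), with the wild-type 0 h array standing below the other 3.

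In LysM-St18flox cells the same question gave Cxcl10, Ifit1 and Gbp5 among the largest values again. Cxcl10 was 1817-fold higher (10.83), Ifit1 657-fold (9.36), Ifit2 420-fold, Gbp5 269-fold and Ch25h 239-fold. Il6 was at least 645-fold higher, Cxcl3 at least 455-fold, Ifnb1 at least 101-fold and Il12b at least 32.1-fold. Among the lower genes, Ankrd37 was 22.9-fold lower, Galnt9 21.3-fold, Zfp395 19.2-fold and Cebpa 17.2-fold.

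Other higher genes in LysM-St18flox cells were Rnd1 (234-fold), Cmpk2 (229-fold), Cxcl1 (223-fold), Il1a (215-fold), Il1b (213-fold), Rsad2 (211-fold) and Ifit3 (195-fold). Ptgs2 was 168-fold higher, Il10 64.3-fold, Nos2 60.4-fold and Tnf 56.3-fold. Lower genes included Smad6 and Frat1 (each 16.3-fold), Lpar6 (15.4-fold), Fhdc1 (15.2-fold), Fut7 (13.1-fold), Lpin1 (12.9-fold) and Gpr146 (12.1-fold). Bmf was 16.9-fold lower by its brightest probe (-4.08), while its second probe gave 0.31. Fbxo32 (at least 47.5-fold), Ces5a (26.2-fold) and Fam214a (20.6-fold) were lower by a bound. The brightest Ces5a probe was well above background only at LysM-St18flox 0 h (-0.03, against at most -4.97 on the other arrays). That bound thus rests on 1 array. Postn, which encodes the matrix protein periostin, was at least 12803-fold higher by 1 of 3 probes, and the other 2 were not well above background on any array. That probe was well above background only at LysM-St18flox 3 h, where its normalized log2 signal of 9.51 was the highest of the array. The value thus rests on 1 probe of 1 array.

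All 18 measured cytokine and chemokine genes (median 5.07) and all 34 measured interferon-stimulated genes (median 4.14) were at least 2-fold higher in LysM-St18flox cells. Feedback inhibitors had 18 of 21 members higher (median 3.05), led by Socs1 at 6.37 and Socs3 at 5.85. These 3 medians were at percentile 100. LPS-induced enzymes and surface molecules had 17 of 21 higher and 1 lower (median 3.02), NF-kB and AP-1 factors 12 of 20 higher and 2 lower (median 1.38), and p53 targets and apoptosis genes 9 of 18 higher and 2 lower (median 0.81). The hypoxia and glycolysis list had a median of -0.21 (percentile 0.02), with 2 members higher and 3 lower. Over the alternative settings that median ranged from -0.36 to -0.13. Of 12976 measured genes, 1054 were at least 2-fold higher and 1164 lower (17.1%), with a median of -0.09 over all measured genes. The bounds added 257 higher and 339 lower genes, and the second probe was past 2-fold in the same direction for 72.3% of 614 genes. With normexp correction, 759 genes were lower.

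The LPS responses of the 2 genotypes share no array. Across 12344 genes measured on all 4 arrays, which are not independent replicates, they correlated at Pearson's r = 0.864 and Spearman's rho = 0.758. Of these genes, 764 were at least 2-fold higher and 773 at least 2-fold lower in both genotypes, against 89.7 and 123 for independent lists of those sizes. In opposite directions were 14 genes.

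**Figure D2:**
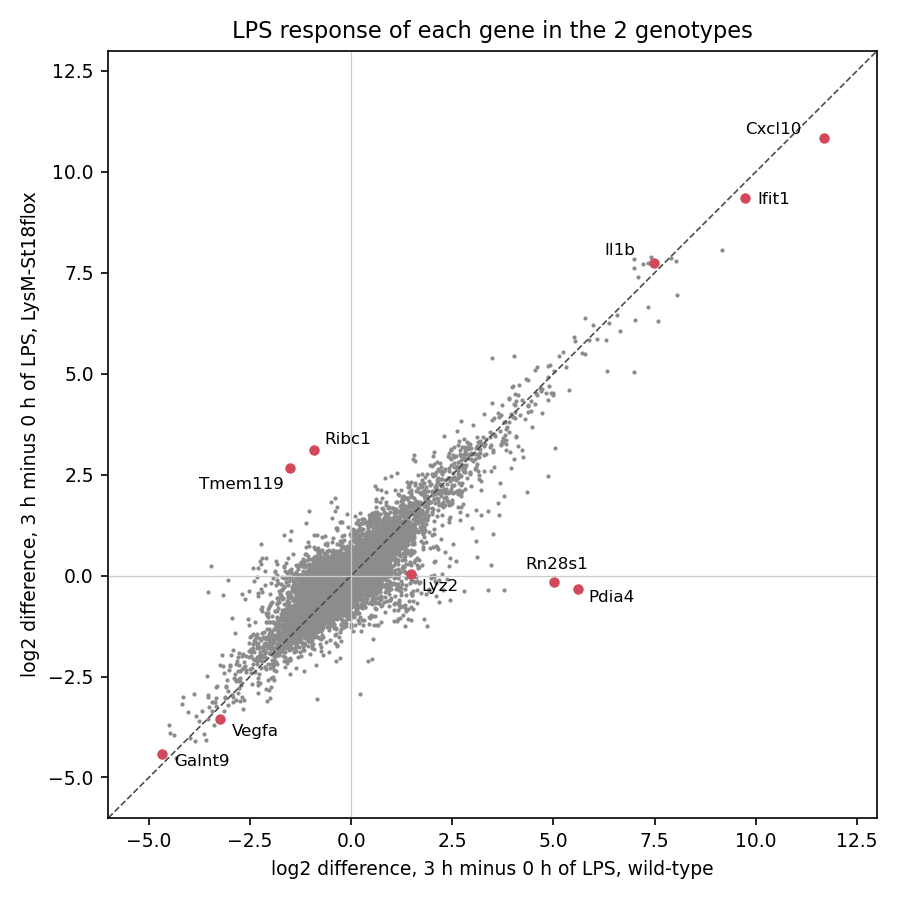
Each point is 1 of 12344 genes measured on all 4 arrays, with the log2 difference between 3 h and 0 h of LPS in wild-type cells on the x axis and in LysM-St18flox cells on the y axis (1 array per group). The dashed line marks equal differences. Cxcl10 lies at 11.70 and 10.83, Vegfa at -3.25 and -3.55, while Pdia4, Rn28s1, Tmem119 and Ribc1 lie away from the line.

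The genotype difference at 0 h asked what differed in unstimulated cells, and genes of other cell types had many of the largest values. The B cell genes Ms4a1 (3.65 on the log2 scale), Pou2af1 (8.94-fold), Fcrla (8.35-fold) and Mzb1 (8.12-fold) and the globin genes Hbb-bt (13.4-fold) and Hbb-b2 (8.75-fold) were higher in LysM-St18flox cells. The neutrophil genes Lcn2 (5.15-fold) and S100a9 (4.77-fold) were lower, while 5 of the 14 measured neutrophil markers were above 0. Interferon-stimulated genes had a median of 0.44 (percentile 100), with 26 of 31 members above 0 and 3 at least 2-fold higher (Gbp5 1.39, Gbp2 1.30 and Oas1g 1.09).

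B cell markers had 9 of 10 measured members at least 2-fold higher (median 2.28), among them Cd79b at 2.36, and 3 more members were higher by a bound of at least 2-fold. Erythroid markers had 4 of 5 higher (median 2.79) and T and NK cell markers 6 of 12 (median 0.90), with Cd2 at 1.74, while Cd4 was lower (-1.04). With the stricter filter on dim probes the T and NK cell median was 0.13. Mast cell markers had 4 of 7 higher (median 1.06), including Cma1 at 2.53 and Cpa3 at 2.24, and their median was 0.64 with normexp correction. Eosinophil markers had 4 of 8 higher (median 0.99), and Siglecf was at 1.19. Large peritoneal macrophage markers, genes of resident cells, had 7 of 20 higher (median 0.68), including Alox15 at 2.30, Tgfb2 at 1.95 and Prg4 at 1.64. With normexp correction that median was 0.42. Each of these 6 medians was at percentile 100. Mesothelial and fibroblast markers had 7 of 10 members lower (median -1.18, percentile 0.00), including Col3a1 at -2.03 and Krt19 at -1.69. Neutrophil markers had 5 of 14 lower (median -0.48, percentile 0.25), including Stfa2l1 at -2.11 and S100a8 at -1.73. Over the alternative settings the neutrophil median ranged from -0.61 to -0.30. Macrophage markers had a median of -0.13 (percentile 31.1), and dendritic cell markers one of 0.42 (percentile 99.1), which was 0.03 without a background filter.

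Genes of antigen presentation by MHC class II had a median of 0.48 (percentile 100), with H2-Aa 3.99-fold higher, H2-DMa at 1.28 and Ciita at 1.20. They moved beside the B cell markers, whose median was 2.28. LPS-induced cytokines and chemokines had a median of 0.00, with 8 members above and 8 below 0, and its side of 0 changed with the scaling. The angiogenic list had a median of -0.32 (percentile 0.81), with Tgfb1 at -1.33, while Flt1 was at 2.65 and Adm at 1.31. Adm had its lowest signal on the wild-type 0 h array (-3.42, against at least -2.10 on the others). At 3 h Adm differed by 0.22, and no measured member of the list was at least 2-fold higher (highest 0.86). Tnf differed by -0.50, Il1b by -0.22, Ptgs2 by -0.17, Nos2 by 0.16 and Lyz2 by 1.20.

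Other genes with large higher values at 0 h were Pdia4 (25.3-fold) and Sdf2l1 (10.4-fold), both of the endoplasmic reticulum, the ribosomal RNA gene Rn28s1 (18.7-fold), Ly6d (7.45-fold), Acy1 (7.27-fold) and Zbtb32 (6.95-fold). For Pdia4, Sdf2l1 and Rn28s1 the wild-type 0 h array stood apart: their normalized signals there were -3.98, -1.17 and 2.95, against at least 0.35, 1.84 and 7.02 on the other 3 arrays. Lower genes were Oas1d (6.50-fold), Cacnb3 (6.20-fold), Sp6 (5.98-fold), Golt1a (5.90-fold), Mrgpra2b (5.58-fold), Sncb (5.52-fold), Abca17 (log2 -2.43), Sva (5.25-fold), Asprv1 (4.97-fold) and Sprr1a (4.73-fold). The 2 probes of Sp6 opposed each other, at -2.58 and 2.68. Bounds were at least 17.2-fold higher for Ces5a, 13.4-fold for Chst8 and 12.2-fold for Spock2, and at least 14.6-fold lower for Olfr1436, 11.6-fold for Fgf3 and 10.8-fold for Emcn. The brightest probes of Ces5a and Chst8 were well above background only at LysM-St18flox 0 h. The Ces5a bound here and its bound after LPS rest on the same value of that array.

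Of 12679 genes measured at 0 h, 385 were at least 2-fold higher and 384 lower in LysM-St18flox cells (6.07%), and 308 higher and 222 lower genes were added by bounds. Of 130 genes with a second measured probe, 30.0% had that probe past 2-fold in the same direction, which left 22 higher and 17 lower genes with 2 such probes. With normexp correction the counts were 229 and 252. The wild-type 0 h array entered this comparison and not the one at 3 h. Its probes disagreed more (0.392, against at most 0.161 on another array), and whether this raised the counts was not tested.

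After 3 h of LPS the genotype difference again had globin and B cell genes among its largest values. Hbb-bt was 14.4-fold higher in LysM-St18flox cells, Hbb-b2 11.5-fold, Hbb-b1 9.73-fold, Hba-a2 9.64-fold and Hba-a1 9.50-fold. Ms4a1 was 8.72-fold higher, Mzb1 8.42-fold, Pou2af1 7.86-fold, Fcrla 7.79-fold and the chemokine receptor gene Cxcr5 7.44-fold. Lower genes included Wfdc21 (9.98-fold), S100a9 (6.69-fold) and Chil1 (5.77-fold), which are abundant in granulocytes, and Mgp (8.15-fold) and Cyp1b1 (6.26-fold), which are abundant in stromal cells. Interferon-stimulated genes had 35 of 36 members above 0 (median 0.39, percentile 100), of which 3 were at least 2-fold higher: Iigp1 at 1.66, Cxcl9 at 1.42 and Ifit2 at 1.22.

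B cell markers had 8 of 10 measured members at least 2-fold higher at 3 h (median 2.24) and 3 more higher by a bound of at least 2-fold. Erythroid markers had 5 of 6 higher (median 3.28), T and NK cell markers 8 of 14 (median 1.12), mast cell markers 4 of 6 (median 1.51), eosinophil markers 2 of 8 (median 0.79) and large peritoneal macrophage markers 5 of 21 (median 0.55). All 6 medians were at percentile 100. With the stricter filter on dim probes the T and NK cell median was 0.10 and that of large peritoneal macrophage markers 0.30. Mesothelial and fibroblast markers had 9 of 11 lower (median -1.39) and neutrophil markers 5 of 14 lower and 1 higher (median -0.42), both at percentile 0.00. The macrophage marker median was -0.06 (percentile 41.0), and that of dendritic cell markers 0.12 (percentile 89.2), which was 0.03 without a background filter and 0.55 in the deposited values.

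MHC class II genes had a median of 0.50 at 3 h (percentile 100), with H2-Aa at 1.33 and H2-DMb1 at 1.04, beside the B cell marker median of 2.24. LPS-induced cytokines and chemokines had 15 members above and 13 below 0 (median 0.01), and the side of 0 again changed with the scaling. Csf3 was at -1.10 and Cxcl3 at -1.06. Ifnb1 differed by 0.70, Nos2 by 0.57, Il6 by 0.18, Ptgs2 by 0.13, Il10 by 0.04, Il1b by 0.02, Tnf by -0.23, Lyz2 by -0.23 and Il12b by -0.52. The hypoxia and glycolysis list had 24 of 30 members below 0 (median -0.26, percentile 0.00), and none was at least 2-fold lower. Its members Ddit4 (-0.92), Pfkl (-0.90), Slc16a3 (-0.57) and Pfkfb3 (-0.54) had the largest differences. At 0 h that list's median was -0.05, on a side of 0 that changed with the scaling. The angiogenic list had a median of -0.22 (percentile 0.17), with Vegfc at -1.31 and Angptl4 at -0.83, and the median was -0.01 with the stricter filter on dim probes.

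Other higher genes at 3 h were Ribc1 (14.8-fold) and Col11a2 (12.7-fold). Other lower ones were Ifnlr1 (12.6-fold), Eef1aknmt (7.92-fold), Samd3 (7.34-fold), Krt39 (7.31-fold), Olfr390 (6.65-fold), Slc4a3 (5.81-fold) and Dgat2 (5.68-fold). Bounds were at least 17.2-fold higher for Trpv1 and 11.8-fold for Il1rl2, and at least 27.5-fold lower for Slc30a3, 26.6-fold for Scgb1b19 and 18.8-fold for Pramel51. Postn was at least 15402-fold higher, by the same single probe on the same LysM-St18flox 3 h array.

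Of 13049 genes measured at 3 h, 237 were at least 2-fold higher and 183 lower (3.22%), with 197 higher and 259 lower by bounds. The second probe was past 2-fold in the same direction for 49.2% of 61 genes, which left 19 higher and 11 lower genes with 2 such probes. With normexp correction the counts were 136 and 96, and 119 genes were lower in the authors' deposited values.

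**Figure D3:**
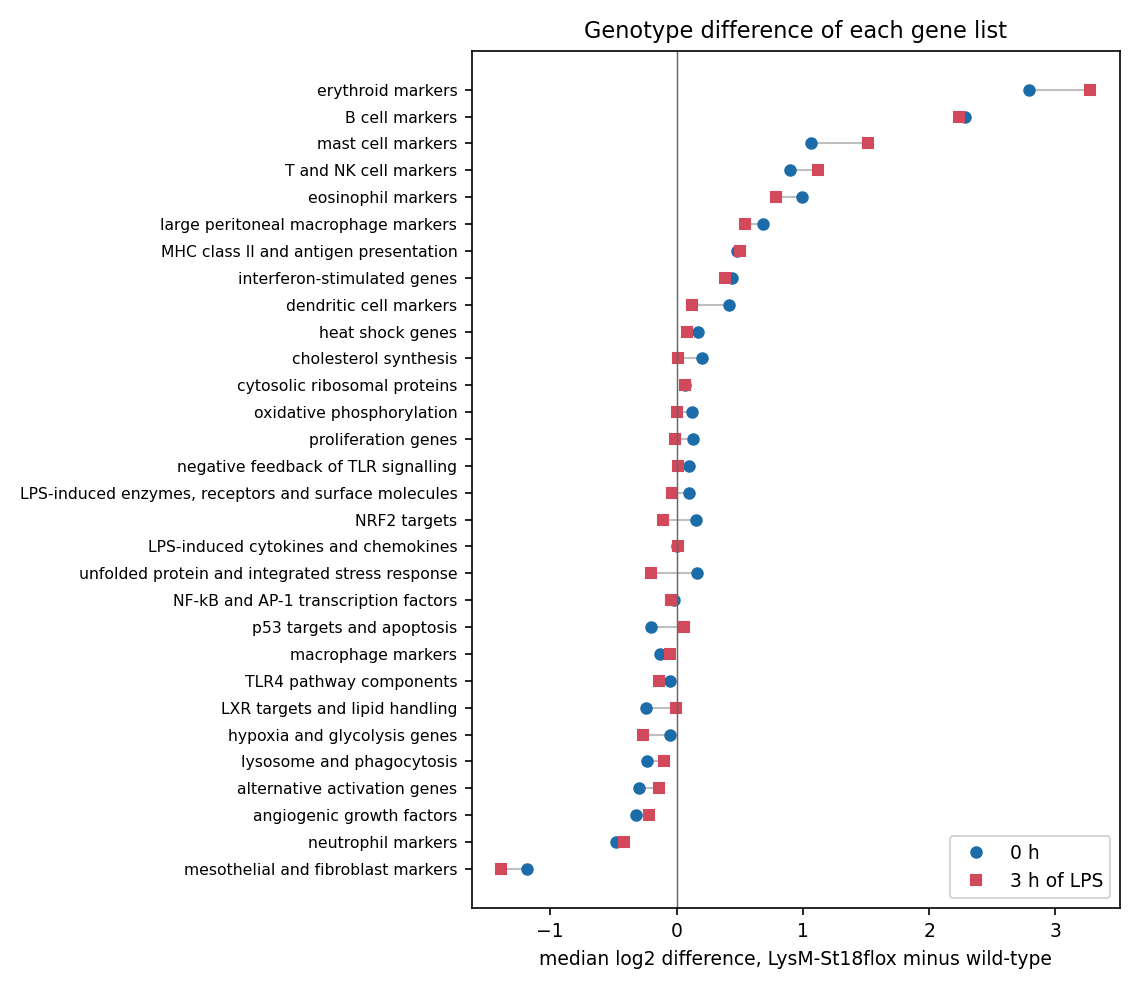
Median log2 difference between LysM-St18flox and wild-type cells (x axis) over the measured genes of each of 30 lists (y axis), at 0 h (circles) and after 3 h of LPS (squares), 1 array per group. Erythroid (2.79 and 3.28) and B cell markers (2.28 and 2.24) lie at the upper end and mesothelial and fibroblast markers (-1.18 and -1.39) at the lower end.

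The genotype differences at the 2 times share no array, and they asked which differences recurred. The 10 genes with the largest differences of one direction at both times were all higher in LysM-St18flox cells. They were the globin genes Hbb-bt, Hbb-b2, Hba-a2 and Hba-a1 and the genes Ms4a1, Mzb1, Pou2af1, Fcrla, Ly6d and Fcmr, which are expressed in B lineage cells. Fcmr, the last of these, was 5.79-fold higher at 0 h and 6.68-fold at 3 h. The globin genes are near-identical pairs, and their probes may not tell the copies apart. Retnla, a gene of alternatively activated macrophages, was also higher at both times (1.80 and 1.94), while the alternative activation list had 14 of 18 members below 0 at 0 h (median -0.30) and 11 of 20 at 3 h (median -0.14). Also higher at both times was the fatty acid desaturase gene Scd1 (2.56 and 2.32). Across 12344 genes, the differences at 0 h and 3 h correlated at r = 0.416 (rho = 0.369). At both times 103 genes were at least 2-fold higher and 56 lower, against 5.68 and 3.62 for independent lists, and 9 genes were opposite. Whether the 0 h and 3 h cells of a genotype came from the same mice is not given in the sources used here. If they did, a difference between lavages would recur at both times, so recurrence is not a second observation of genotype.

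The difference of the LPS responses (LysM-St18flox minus wild-type) asked for which genes the responses lay furthest apart. The lowest values were those of Pdia4 (-5.95), Rn28s1 (-5.17), Sdf2l1 (-4.15) and G6pd2 (-3.74), followed by Dync1li1 (-3.19), Slc4a3 (-3.17), Acy1 (-3.16) and Prcc (-3.06). The highest values were those of Tmem119 (4.16), Ribc1 (4.01), Pcsk1n (3.71), Spata1 (3.01), Ltbp4 (2.95), Uqcc1 (2.69), Abca17 (2.67) and Oas1d (2.63). Pdia4 had a normalized signal of -3.98 at wild-type 0 h against 1.64 at wild-type 3 h, 0.68 at LysM-St18flox 0 h and 0.35 at LysM-St18flox 3 h. Dync1li1 was likewise at -3.16 at wild-type 0 h and at least -0.51 on the other arrays, and Prcc at -2.25 there and at least -0.08 on the others. Other genes stood apart on another array: Acy1 was at 0.12 at LysM-St18flox 0 h and at most -2.53 elsewhere, Slc4a3 at -1.20 at wild-type 3 h and at most -3.35 elsewhere. Ltbp4 was at -4.08 at wild-type 3 h and at least -1.19 elsewhere, and Ribc1 at -0.05 at LysM-St18flox 3 h and at most -3.03 elsewhere. For Uqcc1, which was at -2.48 at wild-type 3 h and at least 0.35 elsewhere, the 3 probes ranged from -0.31 to 2.69.

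Cytokines and chemokines had a median difference of 0.04 between the responses (percentile 57.7) and interferon-stimulated genes one of -0.10 (percentile 6.18). The unfolded protein response list, which holds Pdia4 and Sdf2l1, had a median of -0.24 (percentile 0.10). Nos2 differed by 0.41, Ptgs2 by 0.30, Tnf by 0.27, Il1b by 0.24, Vegfa by -0.30 and Lyz2 by -1.43. Of 12344 genes, 358 had a difference of at least 2-fold above and 297 below 0. The second probe was past 2-fold in the same direction for 17.8% of 101 genes, which left 7 and 11 genes with 2 such probes. With normexp correction the counts were 218 and 166. The wild-type 0 h array, with its larger probe disagreement, entered these counts too.

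**Figure D4:**
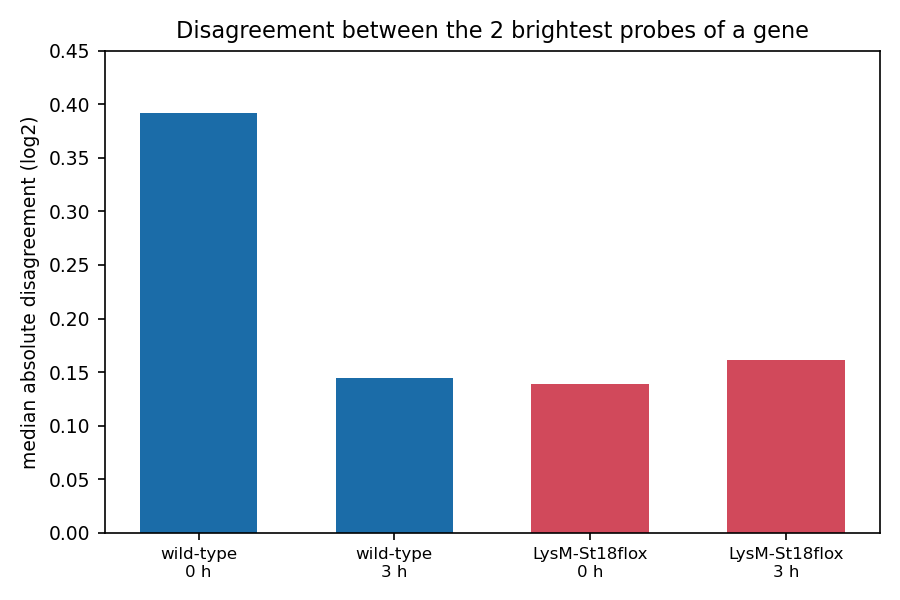
Bars give, for each array (x axis), the median absolute disagreement in log2 units (y axis) between the 2 brightest probes of a gene, measured as the departure of their difference on that array from its median on the other 3, over 4217 genes. The wild-type 0 h array stands at 0.392, against 0.139 to 0.161 for the other 3.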

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

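The tests of other-cell shares, of a lower macrophage share, of the direction of neutrophil markers and of departures across the whole wild-type 0 h array were chosen only after the result was seen. With 1 array per group, none of the differences between genotypes or between times was tested against a spread between mice.

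Tmem119 responded to LPS in opposite directions, at -1.50 in wild-type and 2.66 in LysM-St18flox cells. Its genotype difference was -2.07 at 0 h and 2.09 at 3 h. Both pairs come from the same 4 arrays and differ by 4.16 by construction, so the second is not a separate result. This difference was not tested. Abca17 also responded in opposite directions (-1.67 in wild-type and 1.003 in LysM-St18flox cells, a difference of 2.67), which was not tested. For Golt1a the LPS responses were -1.48 and 1.11, a difference of 2.59 that was not tested. For Cenpf they were 1.14 and -1.13, a difference of -2.27, also not tested.

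The genotype difference of Pdia4 was 4.66 at 0 h and -1.29 at 3 h, a difference of -5.95 that was not tested. G6pd2 had 1.97 at 0 h and -1.77 at 3 h (-3.74), Pcsk1n -1.10 and 2.61 (3.71), and Spata1 -1.17 and 1.85 (3.01). None of these differences was tested. Among probes without a gene symbol here, which no comparison used, 7881 were measured on all 4 arrays. Of them, 446 were at least 2-fold higher after LPS in both genotypes, 465 were lower in both and 8 were opposite.

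Markers of other cell types differed between the genotypes: B cell, erythroid, T and NK cell, mast cell and eosinophil genes were higher in LysM-St18flox arrays, and mesothelial and fibroblast genes lower. A lower macrophage share that raised every other type alike would not give the lower mesothelial and fibroblast markers, whose median was -1.18 at its higher time. These values are part of the pattern to be explained, so they give no independent test. A lower macrophage share with unequal changes of the other types was not tested. Scaling between arrays is argued against by the B cell median, which was 2.04 or more under every scaling at both times, although the mast cell median at 0 h was 0.64 with normexp correction. Different shares of other cells in the lavage samples stay open and may be due to genotype, mouse or handling: 48 of 51 marker genes of these 6 lists (94.1%) had one direction at both times.

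The B cell gene Cd79b had a normalized log2 signal of 3.54 at 0 h and 2.60 at 3 h in LysM-St18flox cells. In wild-type cells it was at 1.18 and 0.32. Some marker genes were dimmer, as Cd5 of the T and NK cell list was at -3.02 at wild-type 0 h. Of the listed genes, 10 of 14 for B cells, 12 of 17 for T and NK cells, 6 of 10 for mast cells, 8 of 11 for eosinophils, 5 of 10 for erythroid cells, 11 of 14 for mesothelial cells and fibroblasts and 14 of 17 for neutrophils were well above background in both wild-type arrays. The T and NK cell median depended on dim probes, and was 0.13 at 0 h and 0.10 at 3 h with the stricter filter. Neutrophil markers, which were not part of the test of 51 genes, had a negative median at both times but one direction in only 7 of 13 genes. Alox15 was on both the eosinophil and the large peritoneal macrophage list. A sort or gate that would remove other cells is not given in the sources used here.

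On the wild-type 0 h array, 192 genes lay at least 1 log2 unit from the other 3 arrays while those lay within 0.5 of each other, against 15, 75 and 15 genes on the other arrays. A damaged region is argued against, as the distance between such spots lay at percentile 58.6 of 1000 random draws. Departures of single probes across the whole array are a candidate explanation, since the 2 brightest probes of a gene disagreed by 0.392, against at most 0.161 on another array. Errors of single probes stay undecided for the 192 genes. For 39 with a second probe, that probe departed by a median of 0.329 times the first (interval 0.234 to 0.578). The median is under 0.5, which the prediction written beforehand took as speaking for such errors. The interval was not part of that prediction and reaches above 0.5. The genes were also picked by the departure of their first probe, which can lower the ratio. A biological state of that one culture was not tested, and it would be expected to move both probes of a gene. For 15 of the 39 genes the second probe departed by at least 0.5 times the first, in the same direction.

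Interferon-stimulated genes were higher in LysM-St18flox arrays at both times, with medians of 0.44 at 0 h and 0.39 at 3 h. Whether it is a list like any other is not decided by its percentile, 100 at the lower of both times. The random lists draw genes singly, while genes of one pathway may vary together. Cytosolic ribosomal protein genes also reached percentile 100 at 3 h, with a median of 0.07. Scaling between arrays is argued against by the lowest median over all scalings, 0.36. A difference in interferon signalling with genotype may remain as a hypothesis, beside variation between mice and RNA of other cells, neither of which was tested for this list.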

How the results depend on the processing

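The count of genes with 2 probes at least 2-fold apart in one direction was chosen only after the result was seen. No paired analysis was possible because each group had 1 array and the labels pair no mice or cultures across groups. A fit of genotype with time as a block would leave 1 degree of freedom and take the interaction as error, and it was not run. Leaving out 1 replicate at a time was likewise not possible with 1 array per group, so no comparison carries a test. The St18 bound was not computed with the mean of all probes, and its brighter probe is absent from the deposited values, so neither gives a value for it.

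The settings were compared over 147 values of at least 2-fold, which were differences of named genes and medians of gene lists. Of these, 145 were still at least 2-fold in the same direction with normexp correction and 146 with quantile normalization. The number was 147 with scaling to the median of detected probes, 146 without a background filter and 144 with the mean of all probes. The deposited values covered 132 of the 147 values, all still at least 2-fold, and the stricter filter 70, of which 69 were. List medians were among the losses. That of mast cell markers at 0 h went from 1.06 to 0.64 with normexp correction. That of T and NK cell markers at 3 h went from 1.12 to 0.10 with the stricter filter. One named difference turned: Sp6 at 0 h was -2.58 by its brightest probe and 0.0506 with the mean of its probes, which opposed each other. No scaling moved the median of all genes by more than 0.1.

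Counts are given as genes higher and then lower, for the LPS response of wild-type cells, that of LysM-St18flox cells, the genotype difference at 0 h and at 3 h, and the difference of the LPS responses. As reported they were 1138 and 1464, 1054 and 1164, 385 and 384, 237 and 183, and 358 and 297. Without a background filter they were 2215 and 2767, 1835 and 2232, 1473 and 1347, 992 and 1039, and 1694 and 1869, as more genes entered. With the stricter filter on dim probes, which admits fewer genes, they were 751 and 491 in wild-type LPS, 362 lower in LysM-St18flox LPS, 86 and 114, 35 and 20, and 90 and 76. At a 1.5-fold threshold they were 2092 and 3204, 1781 and 2717, 1062 and 1592, 663 and 495, and 1290 and 865. At a 3-fold threshold they were 579 and 500, 554 and 375, 140 and 65, 76 and 76, and 74 and 105.

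With normexp correction the LysM-St18flox LPS response had 759 genes lower, the genotype difference 229 and 252 at 0 h and 136 and 96 at 3 h, and the difference of the responses 218 and 166. The offset of 50 shrinks differences of dim probes by construction. The deposited values gave 119 genes lower at 3 h, and the cause was not tested. Requiring 2 probes left 248 and 141, 260 and 184, 22 and 17, 19 and 11, and 7 and 11 genes. Part of this is that a gene then needs a second measured probe. The probes also disagreed: of genes past 2-fold with a second measured probe, 39 of 130 at 0 h and 18 of 101 for the difference of the responses had that probe past 2-fold in the same direction.

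The correlation of the LPS responses was 0.556 without a background filter and 0.921 with the stricter filter, against 0.864 as reported. Genes past the threshold in one direction in both genotypes numbered 1537 as reported, 869 with the stricter filter, 3168 at 1.5-fold and 679 at 3-fold. The correlation of the genotype differences was 0.151 without a filter, against 0.416. Genes in one direction at both times numbered 159 as reported, 96 with normexp correction, 524 without a filter, 31 with the stricter filter, 473 at 1.5-fold and 52 at 3-fold.

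The St18 bound was -2.82 at 0 h as reported, -2.05 with normexp correction and -2.95 with quantile normalization. At 3 h it was -3.08 and, with normexp correction, -1.74. The genotype difference of Vegfa at 0 h was 0.29 as reported, 0.46 with normexp correction and 0.77 with the mean of all probes, and at 3 h it was -0.01 as reported and 0.24 with the mean of all probes. Its dimmest probe, at 2.07 and 0.93, raises that mean. Among spots well above background, signal over local background had a median of 19.4 to 26.3 per array. St18 was not well above background in LysM-St18flox cells, so that median does not describe genes as dim as it. For such genes only bounds can be given.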

Other observations

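Apart from the Poisson limit in the last paragraph, no test in this part was chosen after its result was seen. The written prediction did not hold that limit, and list percentiles describe these arrays only.

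Among unstimulated cells the heat shock genes Hspa1a and Hspa1b were higher in LysM-St18flox cells (2.41 and 2.37), against 0.19 and 0.23 after LPS, while Cryab was lower at both times (-1.70 and -1.42). The wild-type 0 h array carried the difference of Hspa1a and Hspa1b: their normalized signals were 0.45 and -1.55 there, against at least 2.86 and 0.81 on the other 3 arrays. The unfolded protein response list had a genotype median of 0.17 at 0 h (percentile 98.1) and -0.20 at 3 h (percentile 0.27). The value at 0 h was 0.27 with quantile normalization, and its members Pdia4 and Sdf2l1 stood apart on the wild-type 0 h array (-3.98 and -1.17). Toll-like receptor 4 pathway components had a genotype median of -0.05 at 0 h (percentile 36.5) and -0.14 at 3 h (percentile 1.99). Alternative activation genes had one of -0.30 at 0 h (percentile 1.38) and -0.14 at 3 h (percentile 3.51), although Retnla was at 1.80 and 1.94. Cholesterol synthesis genes had one of 0.21 at 0 h (percentile 98.1) and 0.01 at 3 h (percentile 63.0), and cytosolic ribosomal protein genes 0.07 at both times (percentiles 99.4 and 100), or 0.27 at 0 h and 0.12 at 3 h with quantile normalization.

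Of 20 pathway lists, 5 lay in the upper and 2 in the lower 2.5% of matched random lists for the genotype difference at 0 h, and 3 and 4 at 3 h. Of 10 marker lists the counts were 7 and 2 at 0 h and 6 and 2 at 3 h. None of the 7 probes of 4 genes linked to the Y chromosome was well above background on any array. The list of MYT family and SP factors had 3 measured members, with a genotype median of 0.27 at 0 h and 0.00 at 3 h. Another 2 members, St18 among them, were lower by a bound of at least 2-fold at both times, and with these bounds the medians were -0.04 and -0.07.

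A hypothesis was that a passenger segment around the altered gene might differ between the genotypes. Among the 50 measured genes nearest to St18 in the gene order of assembly GRCm38.p6, 2 were at least 1.5-fold apart in one direction at both times (Csprs and Gm4956, named after their values were seen). Over 1110 windows of 50 neighbouring genes the median was 2, and the count that bounds the upper 2.5% of windows was 6. The prediction written beforehand took a count at or under the median of the windows as speaking against such a segment, and the count of 2 met this. The exact Poisson upper limit of that count, 7.22, was not part of that prediction. It includes both the median and the bound of 6, so the number of genes is too small to decide.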
